A study of Rattus norvegicus with 20 samples.

How the data were processed

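Messenger RNA was sequenced from gastrocnemius muscle and abdominal white adipose tissue of 10 rats. Per the labels' protocols, the animals came from a colony of the National Institute on Aging and had 2 weeks to acclimate. RNA was extracted from about 10 mg of muscle or 30 mg of adipose tissue, and 300 ng of it entered a poly(A) library kit. The submitters' processing notes name bcl2fastq, STAR, featureCounts and the rat assembly rn6, without roles or versions. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical genes may thus be split or dropped, which matters most for abundant gene families. The series also concerns open chromatin, and such data were not analysed here.

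The authors deposited a table of expected counts per gene and library, with 32883 genes, of which 23538 were above 0 in at least 1 library. The values are not normalised and need not be whole: 25.3% of the values above 0 were whole within 0.005. They were rounded to whole numbers before the count tests. Samples were grouped by the tissue in the labels. Each column was matched to its sample by name.

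The identifiers are those of Ensembl. The gene table supplied with the reference files has no Ensembl identifiers for this organism, and 0 identifiers matched a name. The gene lists, the shares of myosin heavy chains, the cross-tissue correlation of clock and immediate early genes and the markers of other cell types, all fixed before the data were examined, could therefore not be run. The rule for named genes took, among genes with a symbol, the most abundant genes of each direction with an adjusted p below 0.05, an absolute log2 fold change of at least 3 and no overlap of libraries between the tissues, and also the largest fold changes and members of the lists. Without symbols, the first part was applied to identifiers and limited to 2 per direction.

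Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and muscle was compared with adipose tissue by the robust quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, without the animal as a block. Log2 CPM values for comparisons between libraries used a prior count of 2. Values per library were compared between the tissues by an exact two-sided sign-flip permutation test over 10 animals, whose smallest p is 0.00195. Sets of tissue-restricted genes and their levels were taken from counts scaled by library totals, with TMM-scaled values beside them; other CPM values are TMM-scaled. For numbers of genes, each library was thinned at random to the lowest total of 8446548 reads, and 10 reads were required. Counts are reads without molecular identifiers, so these numbers cover counting error only.

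Libraries with the same number come from the same animal, per the series' design text and the sample titles. In the check of this pairing, deviations from the tissue means over 8303 genes had a correlation between libraries of the same animal of -0.22 to 0.42, with a median of 0.12, against a median of -0.03 between different animals. Of 10 adipose libraries, 2 were closest to their own muscle library, and of 10 muscle libraries, 2 to their own adipose library. The check therefore does not establish the pairing, which rests on the labels. A fit with the animal as a block was run as an alternative. No libraries agreed within sampling noise: the lowest chi-square per degree of freedom was 12.4, for muscle libraries 5 and 10.

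The alternatives tried were relative log expression and upper-quartile factors, library totals alone, the animal block, no filter, a stricter filter (at least 1 CPM in at least 10 libraries), limma-voom (limma 3.58.1), DESeq2 1.42.0, removal of the 20 most abundant genes, glmTreat, and each animal left out in turn. Mitochondrial genes were to be removed with the 20 most abundant ones, which was not possible without names. Unrounded counts, DESeq2 without its replacement of outlying counts, the analyses without adipose libraries 1, 3 and 5 or without muscle library 2, the numbers of genes per library, the restricted gene sets, the 94 genes 20 to 100 times higher in muscle and the correlation of all genes across tissues were added after seeing the data.

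The fit was tested on simulated counts for muscle over adipose with 200 genes changed among 13226 genes tested. Both groups were drawn from the adipose mean profile with the real scaled library sizes. The simulation therefore could not test the scaling where most genes differ, as between these tissues. It called 12.1% of genes changed 1.41-fold, 67.2% of those changed 2-fold and 94.0% of those changed 4-fold, and 7 of its 123 calls were unchanged genes. For a simulated mix of 1% muscle in the adipose profile, the level of 170 muscle-restricted genes, scaled by library totals, gave 1.21%. For 2000 simulated genes with a true ratio of spreads of 2, the ratio was 1.98, and for a true cross-tissue r of 0.7 the median r over 2000 genes was 0.72. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.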

Results

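RNA was measured in 2 tissues of the same rats: gastrocnemius, a mixed muscle of the calf, and white adipose tissue from the abdomen. The animals were 8-month-old rats of a Fischer 344 by Brown Norway cross. The 20 libraries comprised 10 of muscle and 10 of adipose tissue, and libraries with the same animal number came from the same rat. The series' design text speaks of 5 males and 5 females, whereas each sample label says male. No sample was therefore assigned a sex, and no comparison by sex was made. Total counts per library ran from 8446548 to 20141701 in muscle and from 11067641 to 25904168 in adipose tissue. The mean total was 16103500 ± 3330770 (SD, n = 10) in muscle and 15411694 ± 4298870 (SD, n = 10) in adipose tissue. The difference was smaller than either SD and was not past the test (exact sign-flip permutation test over animals, two-sided, p = 0.713). The deposited table lists genes by Ensembl identifier, and the files used here do not pair these identifiers with names. Gene groups are therefore described by where and how strongly they were expressed, and 2 identifiers are printed for each direction.

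The first comparison asked how the transcripts of each tissue were distributed over genes. Muscle transcripts were concentrated in few genes. The 10 most abundant genes of a library took 32.7% ± 2.15 (SD, n = 10) of the counts in muscle and 17.5% ± 6.17 (SD, n = 10) in adipose tissue. The share was higher in muscle in 10 of 10 animals (exact sign-flip permutation test, two-sided, p = 0.00195, the smallest this design allows). The most abundant gene alone took 9.67% ± 2.27 of muscle counts and 4.09% ± 2.08 of adipose counts (SD, n = 10). The 100 most abundant genes took 64.0% ± 2.89 of muscle counts and 36.3% ± 6.61 of adipose counts (SD, n = 10). Adipose library 3 had a share for its 10 most abundant genes of 32.6%, close to the 33.7% of the muscle library of the same animal, while the other adipose libraries lay between 9.50% and 20.97%. The genes at least 8-fold higher in muscle, described below, took at most 2.49% of the counts in any adipose library. The likeness is therefore one of concentration and not of muscle transcripts.

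More genes reached a fixed number of reads in adipose tissue than in muscle. With each library thinned to 8446548 reads, 13746 ± 452 genes had at least 10 reads in adipose tissue and 11311 ± 211 in muscle (SD, n = 10). Adipose tissue had more such genes in 10 of 10 animals (exact sign-flip permutation test, two-sided, p = 0.00195). A group of 9334 genes reached this level in all 20 libraries. A further 755 genes reached it in all 10 adipose libraries and in no muscle library, and 92 genes in all 10 muscle libraries and in no adipose library. The group found in muscle alone had 150 genes when adipose libraries 1, 3 and 5 were left out. Leaving libraries out can only keep or enlarge such a group, and no other sets of adipose libraries were tried. Without muscle library 2 the muscle group had 112 genes and the adipose group 861. The sizes of both groups depend on the fixed cut of 10 reads. Where few genes take most of the counts, as in muscle, other genes reach it less easily. The 100-fold criterion for restricted genes, described below, gave 170 muscle and 154 adipose genes by library totals. With TMM factors it gave 235 and 79, so the excess of adipose genes does not hold under each criterion. In adipose libraries 1, 3 and 5 muscle-restricted transcripts were higher than in most other adipose libraries, at levels described with the restricted genes. Among the 20 most abundant genes of each tissue, 9 were shared. These 9 genes took 15.1% ± 2.97 of muscle counts and 13.7% ± 6.52 of adipose counts (SD, n = 10).

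**Figure D1:**
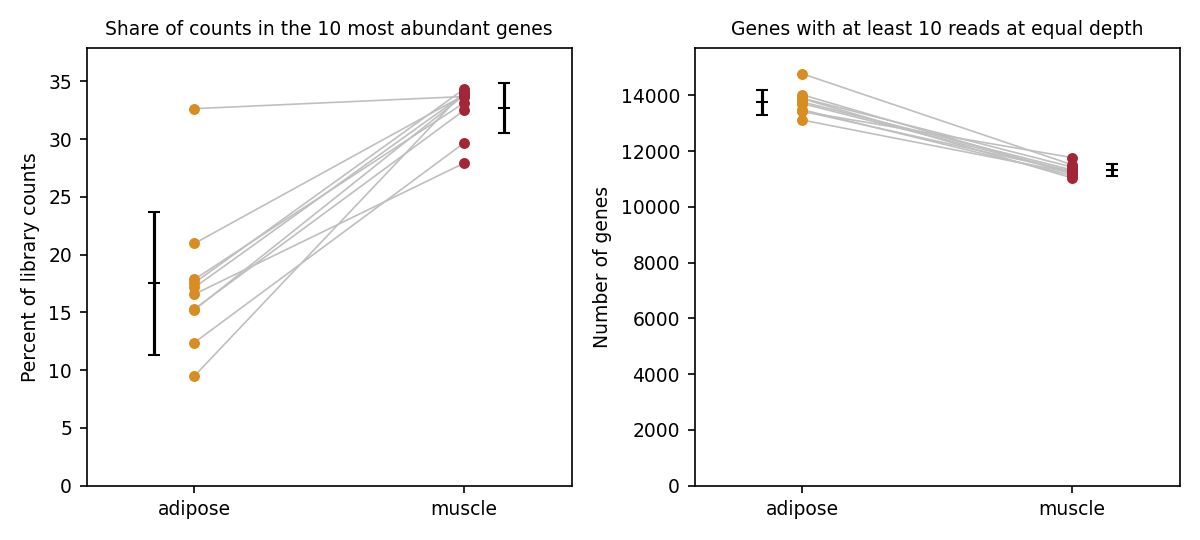
Share of library counts in the 10 most abundant genes (left, percent) and number of genes with at least 10 reads after thinning to 8446548 reads (right). Each point is a library, grey lines join the libraries of an animal, and bars give the mean and SD of 10 libraries. In all 10 animals the share was higher in muscle and the number of genes higher in adipose tissue.

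The second comparison, muscle against adipose tissue in the same animals, asked which genes differed in level between the tissues. Of 13806 genes tested, 11011 differed, or 79.8% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these genes, 5187 were higher in muscle and 5824 higher in adipose tissue, with a median absolute log2 fold change of 1.48. At least a 2-fold difference was estimated for 7442 of them, 3213 higher in muscle and 4229 higher in adipose tissue. At least an 8-fold difference was estimated for 806 genes higher in muscle and 1236 higher in adipose tissue, and at least a 100-fold difference for 251 and 136 genes. A test against a 2-fold difference itself (edgeR glmTreat) called 6175 genes, 2544 higher in muscle and 3631 higher in adipose tissue. In 6276 of the called genes, the 10 muscle libraries and the 10 adipose libraries did not overlap, where chance would give 0.00108% of the tested genes for free assignment of the 20 libraries, and at most 0.195% for exchange of the tissues within animals. Of the genes without overlap, 2896 were higher in muscle and 3380 higher in adipose tissue.

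The genes that were at least 8-fold higher in muscle dominated its transcripts. They took 53.8% ± 4.74 of the counts in muscle libraries and 1.66% ± 0.361 in adipose libraries (SD, n = 10). The genes at least 8-fold higher in adipose tissue took a smaller part of that tissue, 21.6% ± 3.33 of adipose counts, and 0.40% ± 0.13 of muscle counts (SD, n = 10). With the sets defined under library totals in place of trimmed-mean (TMM) factors, these shares were 49.4% ± 5.45 of muscle counts and 33.9% ± 3.46 of adipose counts (SD, n = 10). The muscle share was the larger in 10 of 10 animals under either scaling. Much of it lay in few genes: with the 20 most abundant genes left out of the sets but kept in the totals, the shares were 28.1% ± 2.51 and 20.4% ± 3.12 (SD, n = 10). The muscle share was then again the larger in 10 of 10 animals. Across genes, the mean log2 levels of the 2 tissues had r = 0.58 and rho = 0.65; genes are not independent replicates. Between libraries, r across genes was 0.91 to 0.98 within muscle, 0.83 to 0.98 within adipose tissue and 0.50 to 0.61 between the tissues.

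The balance of the directions depended on the scaling. With library totals, fold changes shifted towards adipose tissue by a median of -1.30 on the log2 scale. Of 11932 called genes, 1692 (14.2%) were then higher in muscle and 10240 higher in adipose tissue, beside the 5187 (47.1%) and 5824 above. The genes with at least an 8-fold difference were then 473 higher in muscle and 3019 higher in adipose tissue, and those with at least a 100-fold difference 194 and 252. The 9 genes abundant in both tissues had a median log2 fold change of 1.37 with TMM factors, where all 9 lay above 0, and of 0.15 with library totals, where 8 of 9 did.

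**Figure D2:**
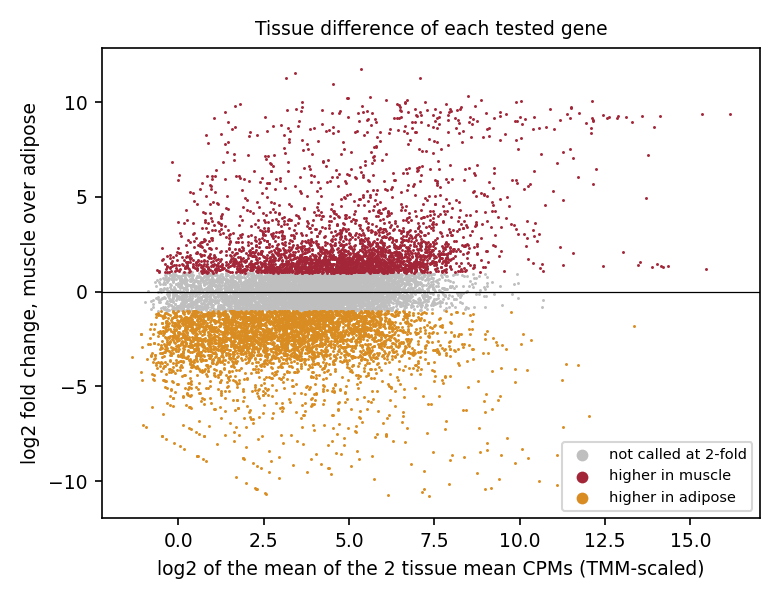
Log2 fold change of muscle over adipose tissue against the log2 of the mean of both tissues' mean CPM (TMM-scaled), 1 point per tested gene. Red and orange points are the 3213 and 4229 genes called with at least a 2-fold difference, higher in muscle and in adipose tissue, and grey points are the other tested genes.

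Among genes called without overlap and with at least an 8-fold difference, the most abundant in muscle was ENSRNOG00000049695. It reached 145680 ± 57369 CPM (read counts scaled by library total and TMM factor) in muscle and 218 ± 421 in adipose tissue (SD, n = 10), a log2 fold change of 9.38 (SE 1.24, edgeR adjusted p = 4.08e-07). Muscle library 2 held 5640 CPM of it, the lowest muscle value. The next, ENSRNOG00000017786, reached 81977 ± 7860 CPM in muscle and 126 ± 221 in adipose tissue (SD, n = 10), a log2 fold change of 9.35 (SE 1.07, edgeR adjusted p = 4.49e-08). The adipose levels of both genes had SDs above their means, and their log2 fold changes were 13.03 and 12.58 without adipose libraries 1, 3 and 5, 11.57 and 11.57 with the animal as a block, 11.31 and 11.33 with limma-voom, and 4.57 and 3.39 with DESeq2's default handling of outlying counts. Both genes were higher in muscle in each of these fits.

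The most abundant gene of this kind in adipose tissue was ENSRNOG00000010805, with 8318 ± 2881 CPM in adipose tissue and 89.1 ± 18.5 in muscle (SD, n = 10). Its log2 fold change was -6.54 (SE 0.29, edgeR adjusted p = 6.55e-15). ENSRNOG00000018991 followed with 6255 ± 2364 CPM in adipose tissue and 429 ± 144 in muscle (SD, n = 10), a log2 fold change of -3.87 (SE 0.26, edgeR adjusted p = 7.05e-12). With library totals the log2 fold changes of these adipose genes were -7.79 and -5.15.

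Genes that were nearly restricted to 1 tissue were followed in the other. For this, counts were scaled by library totals alone. On that scale a set of 170 genes had a median of at least 20 counts per 1e6 reads in muscle and at least 100 times the adipose median, and 154 genes met the same criterion for adipose tissue. With TMM factors 235 and 79 genes would meet it, which include all 170 of the muscle set and 79 of the adipose set. In adipose libraries 1, 3 and 5 the muscle-restricted genes stood at a median of 1.41%, 1.57% and 0.454% of their muscle level. In adipose library 4 the median was 0.149%, and the 90th percentile of these genes was 4.60%. In the remaining 6 adipose libraries the median was 0.0265% to 0.136%. The adipose-restricted genes stood at 0.208% to 0.393% of their adipose level in 9 muscle libraries and at 0.533% in muscle library 2. With TMM factors the levels were 0.529%, 0.815% and 0.174% in adipose libraries 1, 3 and 5, 0.0461% in library 4 and 0.0112% to 0.0518% in the remaining 6, and 0.530% to 0.948% in 9 muscle libraries and 1.09% in muscle library 2. The median log2 fold change, with TMM factors, was 9.07 over the 168 muscle-restricted genes that were tested and -6.76 over the adipose-restricted genes. Without adipose libraries 1, 3 and 5 these medians were 10.93 and -6.82. With library totals they were 7.84 and -8.07, so which set had the larger fold change depended on the scaling.

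**Figure D3:**
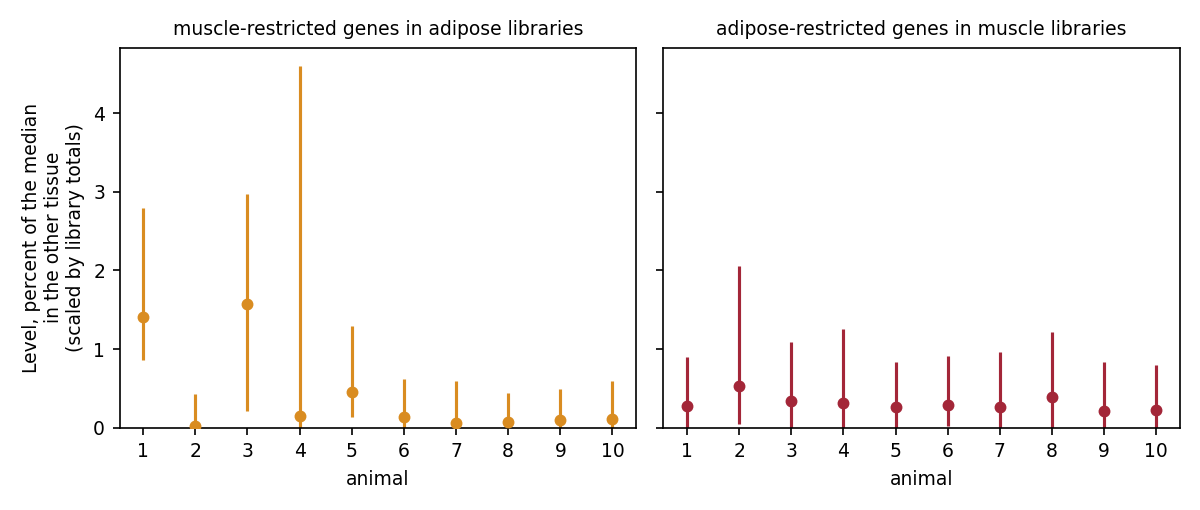
Level of the 170 muscle-restricted genes in adipose libraries (left) and of the 154 adipose-restricted genes in muscle libraries (right), in percent of the gene's median in the other tissue and scaled by library totals, for animals 1 to 10. Points are medians over genes and lines run from the 10th to the 90th percentile of genes. Adipose libraries 1 and 3, at 1.41% and 1.57% on this scale (0.529% and 0.815% with TMM factors), stand above the other adipose medians.

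The last comparison asked in which tissue libraries of different animals differed more. Over 8303 genes with a mean of at least 5 CPM in both tissues, the median absolute deviation from the tissue mean was 0.220 ± 0.082 in adipose libraries and 0.181 ± 0.049 in muscle libraries on the log2 scale (SD, n = 10). It was higher in adipose tissue in 6 of 10 animals. The mean difference was 0.0395 (SD 0.0891 over animals) and was not past the test (exact sign-flip permutation test, two-sided, p = 0.189). Without animal 2, whose muscle library had the largest deviation in its tissue, the difference was 0.0576 (same test, p = 0.0508).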

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

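The tests of explanations in this part were chosen after the results were seen, except that the bounds for the 94 genes used to test adipose libraries 1, 3 and 5 were set before those genes were examined. For 20 groups of 10 libraries (6 measures per library and the levels of 4 genes, in each tissue), the highest and the lowest library was compared with its neighbour. In 7 cases the gap, divided by the group's range, exceeded Dixon's 95% critical value for 10 samples. Chance gives about 1 in 20 groups.

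Muscle library 2 was set apart in 3 of these cases. Its median deviation from the tissue mean was 0.311 on the log2 scale, next to 0.205 for the nearest muscle library. Its mean correlation with the other muscle libraries was 0.925, next to 0.957. Its level of ENSRNOG00000049695 was 12.46 on the log2 CPM scale, next to 16.49. In this library 170 genes stood at least 2-fold above and 310 at least 2-fold below each of the other 9 muscle libraries, while in the other muscle libraries these numbers were at most 11 and 14.

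Low depth is argued against, since the library's total of 16480287 lies above the 15946760 that was the median of the other 9, and so is adipose tissue mixed into the sample, since the level of adipose-restricted genes in this library would supply, at the median, 0.192% of the level of the 170 raised genes. Across the 480 genes, which are not independent replicates, the deviations of library 2 had r = 0.89 with those of muscle library 8, 0.61 with 7 and 0.40 with 1, and -0.32 to -0.65 with those of the other 6, each from a separate set of 4 libraries. Negative values follow in part from taking deviations from means of the other libraries, so they decide nothing. Library 2 may lie at the end of a variation that muscle library 8 shares most, for which the portion of the muscle taken is a candidate that was not tested. A sample from another animal cannot be told apart from this, because the genes that correlate across tissues ranked the own adipose library first in only 2 of the other 9 animals, and 9 of 10 for animal 2.

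The muscle-restricted genes stood higher in adipose libraries 1 and 3 than in the rest. They were at 1.41% and 1.57% of their muscle level by library totals (0.529% and 0.815% with TMM factors). The lower of these was 11.4 times the median of all 10 adipose libraries, 0.123% (11.6 times with TMM factors). Spill-over during sequencing that is even over the adipose libraries would not give such unequal levels. Libraries 1 and 3 were picked for standing higher, so this outcome was fixed in advance. It decides nothing about spill-over in general, and uneven spill-over was not tested. Skeletal muscle RNA mixed into the libraries was tested on 94 other genes, 20 to 100 times higher in muscle, which had not been used to pick the libraries: their median rise over the mean of adipose libraries 2 and 6 to 10 was 1.06 times in library 1 (quartiles 0.246 and 1.78), and 0.912 times in library 3 (quartiles 0.429 and 1.34), what the share estimated from the restricted genes gives (0.481% and 0.771% with TMM factors, above the level in those 6). In these libraries 80.9% and 85.1% of the genes lay above that mean. In those 6 libraries it was 39.4% to 53.2%, each being set against the mean of the others of the 6. Adipose library 4, with an estimated share of 0.00416%, had 75.5%, so this percentage alone is not specific to muscle. The shares of 0.481% and 0.771% are relative to TMM-scaled muscle levels and are not fractions of a library's reads. By library totals the restricted genes stood at the 1.41% and 1.57% given above. The size of the median rise in libraries 1 and 3 goes with a mixture of muscle RNA. Whether it entered at dissection or later stays open. In library 5 the median rise was 0.837 times that predicted, with 63.8% of the genes above, and muscle RNA cannot be told apart there from other variation. In library 4, 41.2% of the restricted genes lay above their level in each of those 6 libraries. In libraries 1, 3 and 5 this was 94.7%, 85.9% and 73.5%. The bound for this percentage was set after the data were seen. In library 4 the median level of the restricted genes was 0.149% beside a 90th percentile of 4.60%. These values argue against a general admixture of muscle as the origin of its highest levels. A smaller admixture is not excluded.

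The third pattern is the lower number of genes in muscle. The counts taken by the 100 most abundant genes of each library are argued against as the whole cause. Concentration of counts in further genes was not tested. With the 100 most abundant genes of each library left out and the rest thinned to 3042573 reads, muscle still had fewer genes with at least 10 reads, by -1486 ± 295 (SD, n = 10), in 10 of 10 animals, instead of -2435 ± 470. The tissue itself, which the design compares, remains among the open explanations.

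The other cases are given as values. Adipose library 5 had a total of 25904168, next to 18622945, and muscle library 7 one of 8446548, next to 14141428. Adipose library 3 had 32.6% of its counts in its 10 most abundant genes, next to 20.97%. Adipose library 4 had 11.19 log2 CPM of ENSRNOG00000010805, next to 12.51.

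Chance assignment of the tissue labels is argued against as the source of the tissue difference, which was hardly in doubt for 2 different tissues. The comparison used 100 of 512 possible assignments and does not bear on the scaling. Of 100 assignments of the tissue labels within animals, each of which separates all 10 pairs as the real one does, 1 gave as many genes as the 11011 observed, the real one itself, and the highest of the others gave 9266. For differences of at least 2-fold, 1 of 100 gave as many as the 7442 observed, and the highest of the others gave 5742. The highest of the others exchanged the tissues of 1 animal only.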

How the results depend on the processing

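The fits with unrounded counts, with DESeq2 free of outlier replacement or with doubted libraries left out, and the settings for composition and number of genes, were chosen after seeing the data. In all 88 recomputations made of them, the headline results met the rule set for each. For the 2 counts of genes the rule was to stay within 1.5 times, which does not check the direction of any gene. The differences in spread, composition and number of genes kept their direction, and their tests their side of the threshold. For spread that side was p above 0.05 in the sign-flip test. The number of genes called ranged from 10566 with the stricter filter to 13894 without a filter, and from 10702 to 11067 with an animal left out; at 2-fold or more it ranged from 6175 with glmTreat to 10550 without a filter, and from 7386 to 7591. Of the 11011 genes, 10746 were called in the same direction with the animal as a block (10990 genes called) and 7516 with library totals. Upper-quartile scaling shifted the median by -0.18 (log2) and gave 41.4% of calls higher in muscle. The counts were 10967 without adipose libraries 1, 3 and 5 and 11363 without muscle library 2. The difference in spread stayed between 0.0173 (without animal 4) and 0.0576 (without animal 2) with an animal left out. The sign-flip p ran from 0.0508 without animal 2 to 0.551 without animal 4. The 4 named genes kept their direction and their call in each fit that held them, the block included. They had been picked from these data for a large difference without overlap of the tissues, so this stability is no separate support. The removal of the 20 most abundant genes took out 3 of them. The low DESeq2 fold changes of the muscle genes come from its replacement of outlying counts: without it they were 9.40 and 9.37 in place of 4.57 and 3.39. Such replacement touched 553 genes and moved the log2 fold change by over 1 in 472 of them. The alternatives for gene lists, myosin shares and clock genes were not run, for want of gene names. The simulation called 12.1% of 1.41-fold changes when 200 genes changed. In the real data, 77.6% of the 1291 genes with an estimated absolute log2 fold change of 0.4 to 0.6 were called. With most genes called, the adjusted threshold is less strict. The first percentage covers genes with a known change and the second genes picked by their estimate. They were not compared at a common threshold, so how much the threshold accounts for is not known.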

Other observations

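The tests and gene sets of this part were chosen after the data were seen. Whether animals high for a gene in one tissue were high for it in the other was examined for 8303 genes over 10 animals. A correlation of at least 0.8 was found for 67 genes, against a median of 18 when animals were paired at random across tissues. Of 100 pairings, the real one included, 5 gave as many genes, and the highest gave 140, so chance pairing of animals is not excluded as the source. The number depended on the setting. With rho it was 84 (4 of 100 pairings as many), with library totals 28 (32 of 100), and for genes of at least 50 CPM 23 (3 of 100). Without animal 2, the animal whose muscle library stands apart, it was 182 (1 of 100). Without animals 4, 6, 8 and 9 in turn it was 101, 105, 131 and 121, with 5, 8, 7 and 6 of 100 pairings giving as many. Without animals 1, 3, 5, 7 and 10 in turn it was 73, 94, 100, 66 and 87, with 19, 8, 8, 20 and 11 of 100. With 9 animals random pairing itself gave more genes, a median of 30 without animal 2 and of 32, 36, 32 and 32 without animals 4, 6, 8 and 9. Without animals 1, 3, 5, 7 and 10 this median was 36, 33, 33, 31 and 34.

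The gene with the highest correlation, ENSRNOG00000021027, was chosen after its values were seen. It had r = 0.976 and rho = 0.952 over 10 animals (permutation test, two-sided, p = 7.0e-05 for each before adjustment over the 8303 genes), and r = 0.93 without animals 2 and 4. Its level ranged over animals from 32.2 to 227 CPM in adipose tissue and from 41.1 to 232 CPM in muscle, while the tissues did not differ by the test (log2 fold change -0.01, edgeR adjusted p = 0.974). In 1 of 100 pairings, the real one, the highest r was this high, but with rho 37 of 100 pairings gave as high a value.

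Adipose library 4 carried 224 genes at least 2-fold above each other adipose library, 27 of them at least 8-fold, and 72 at least 2-fold below. Adipose library 3 carried 32 such genes above and 113 below. The remaining adipose libraries had at most 19 above and 63 below.

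The animals were also split in all 126 ways into 5 and 5, and the genes counted whose levels did not overlap between the 2 sets, in the same direction in both tissues. In 90 splits there were 0 such genes. The highest numbers were 22, for animals 1 to 5 against 6 to 10, and 20, for animals 1, 3, 6, 9 and 10 against the rest. In these splits 0 and 2 genes went in opposite directions in the 2 tissues. The series' design text speaks of 5 males and 5 females, while each sample label says male. No label names these sets of animals, so whether either matches the sexes cannot be told. They were not used to group samples.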
